A study of Homo sapiens with 30 samples.

How the data were processed

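The study measured RNA levels in HCT116 cells, an established line from a colon adenocarcinoma, in a wild-type form (WT) and in an isogenic form without p53 (p53KO), a transcription factor that DNA and ribosomal stress activate. Per the labels, cells were seeded overnight and then left untreated or kept for 16 hours in 1, 10 or 100 nM actinomycin D, a drug that binds DNA and blocks transcription, at the lowest doses mainly that of ribosomal RNA, or in 4 µM nutlin-3, which frees p53 from its inhibitor MDM2. Each of the 10 groups had 3 arrays, 30 in all, and the labels do not say whether these came from separate cultures, so p-values measure only the spread between arrays, which may be technical. Total RNA was amplified and labelled for Illumina bead arrays.

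The raw table holds, per the file headers, an average bead signal as a linear intensity and a detection p-value per probe and array, as the authors deposited them from BeadStudio, named in the submitters' processing notes, whose version is not given in the sources used here. The processed table and the series matrix hold a second deposited intensity per probe, with values below 0 and the same median, 10.195, on every array, so a background was subtracted and the arrays were scaled alike. The method is not given in the sources used here. The 22177 matrix values per array matched the processed table, and that match tied each probe to its annotation. The tables also hold the columns of 26 arrays of other samples, not used here.

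Of the 22177 probes, 21101 had 1 gene symbol, 1076 had none and 0 had several. Symbols were updated through gene IDs for 20986 probes. Raw intensities were background-corrected and normalised with limma 3.58.1 in R 4.3.3 (neqc with negative controls inferred from the detection p-values, offset 16, quantile normalisation, log2). A probe was kept where its detection p was under 0.01 on all 3 arrays of at least 1 group, which left 12896 probes. Each gene was represented by the kept probe with the highest mean, which gave 11526 features, 10919 with a symbol and 607 without. BTG2 had no tested probe and is not analysed here. Results for 1 further gene are not reported here.

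All 30 arrays entered 1 linear model with a mean per group (lmFit, contrasts.fit and eBayes, 20 residual degrees of freedom). Fold changes are log2 differences of group means with the moderated standard error (SE), and every adjusted p for a gene is limma's, with Benjamini-Hochberg adjustment over the 11526 features of a contrast. A gene was called at an adjusted p under 0.05. Where a probe was not detected on any array of 1 group, its fold is given as a bound, from the bright group's mean over the mean of the dim group, each dim value raised to the lowest signal of any detected probe on its array. The 15 contrasts set each treatment against the untreated cells of its genotype (8), the responses of WT and p53KO cells against each other as an interaction (4), and WT against p53KO untreated cells, 1 nM actinomycin D against nutlin in WT cells, and 100 nM against 1 nM in WT cells. In 15 gene lists fixed before the data were examined, limma's camera compared each list with all other genes (preset correlation 0.01, adjusted over the 15 lists of a contrast), beside camera with an estimated correlation and fry. The lists were 3 of p53 targets (arrest and feedback, apoptosis, repair and metabolism), mitosis and G2/M, DNA replication and S phase, immediate early genes, ribosomal proteins, RNA polymerase I and ribosome biogenesis, NF-kB and inflammatory genes, interferon response, integrated stress and unfolded protein response, heat shock proteins, cholesterol synthesis, colon epithelial markers and markers of other cell types. The genes named were set by rule before the data were examined: in each contrast the 5 highest and 5 lowest called genes whose 3 values in 1 group all lay outside the range of the other group, up to 4 called members per list, and CDKN1A, MDM2, GDF15, BAX, FAS, TP53I3, PLK1, CCNB1, CDK1, MYC, FOS and MCL1. Genes named outside that rule are said to be so.

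The arrays lay on 7 slides. All 1 nM arrays shared slide 3 with no other group. The 10 and 100 nM arrays shared slides 1 and 5, and the untreated and nutlin arrays lay on slides 2, 4, 6 and 7. Treated and untreated arrays met on 1 slide only for nutlin, on slide 2. For actinomycin D against untreated cells of a genotype, the slide could therefore enter only as a random block (duplicateCorrelation, correlation 0.501). In the interactions and for WT against p53KO cells it could also enter as a fixed block. Replicate numbers tied the genotypes within a treatment: the deviations of the WT and p53KO arrays of the same number from their group means correlated at 0.6 or more across genes in untreated cells (lowest of 3 pairs), at 0.41 at 1 nM, 0.35 at 10 nM and 0.23 at 100 nM, but at -0.44 for nutlin. Deviations within a group cancel out in each gene, so the 3 correlations of a treatment are not independent. In untreated cells the deviation shared by the first arrays enters all 3. The pairing comes from the data, not from the labels. Nor do the slides give it, since the second arrays at 10 and 100 nM and the third nutlin arrays lay on different slides in the 2 genotypes. Numbers did not tie treated to untreated arrays, where the lowest correlation of a contrast ran from -0.17 to 0.03.

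After the data were examined, 4 arrays were doubted: the third nutlin arrays of both genotypes, which went against their genotype labels, and the first untreated arrays of both genotypes, which stood apart from the other untreated arrays. All arrays keep their labels in every main value. Values without these 4 arrays, and with WT and p53KO arrays of the same treatment and number as pairs, were chosen after seeing the data and are given for part of the results. Single-slide fits and the values without the first untreated arrays were also chosen after seeing the data, while leaving out the third nutlin arrays had been set for the nutlin comparisons from their slides. Other alternatives, set before the data were examined, were 75th percentile scaling, no background correction, an offset of 50, both processed tables (values under 1 set to 1), no filter, detection on all 30 arrays, all probes, only the groups of the contrast, a trend with robust fitting, array weights (estimated gene by gene, since the default estimate did not converge), slide and replicate blocks, leaving out the second 10 and 100 nM WT arrays, and leaving out each array. The number of arrays limits the precision.

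The fit was tested on simulated data with the real means and spread, 11526 genes and 200 changed genes in each of 10 simulations. For 1 nM actinomycin D in WT cells it recovered 31.2% of genes changed 1.5-fold, 82.7% at 2-fold and 99.2% at 4-fold, with 5.97% false among all calls. For the interaction at 1 nM it recovered 5.67%, 50.7% and 95.5% of genes with those folds. The noise was drawn independently for each array, with no slide or pair effect. These shares therefore do not cover slide effects, and all real 1 nM arrays lay on a slide of their own. Figures were drawn with matplotlib.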

Results

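Expression was measured on 30 Illumina bead arrays of HCT116 cells with and without p53, 3 for each of 10 combinations of genotype and treatment. The design asks what actinomycin D and nutlin change in cells that differ in p53. Untreated WT arrays had a raw 75th percentile of 259.9 ± 17.2 intensity units (SD, n = 3) and 12352 ± 185 detected probes, and untreated p53KO arrays 221.3 ± 28.3 and 12215 ± 137. At 100 nM actinomycin D the 75th percentile was 120.9 ± 13.5 in WT and 108.4 ± 8.6 in p53KO cells, and detected probes were 10558 ± 228 and 10238 ± 145. An exact permutation test of each measure gave p = 0.1 in each genotype, the smallest 3 against 3 allow, and p = 0.005 over both genotypes with arrays exchanged within genotype (two-sided). At 1 and 10 nM and with nutlin, the mean 75th percentile was 0.911 to 1.29 times that of untreated cells.

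**Figure D1:**
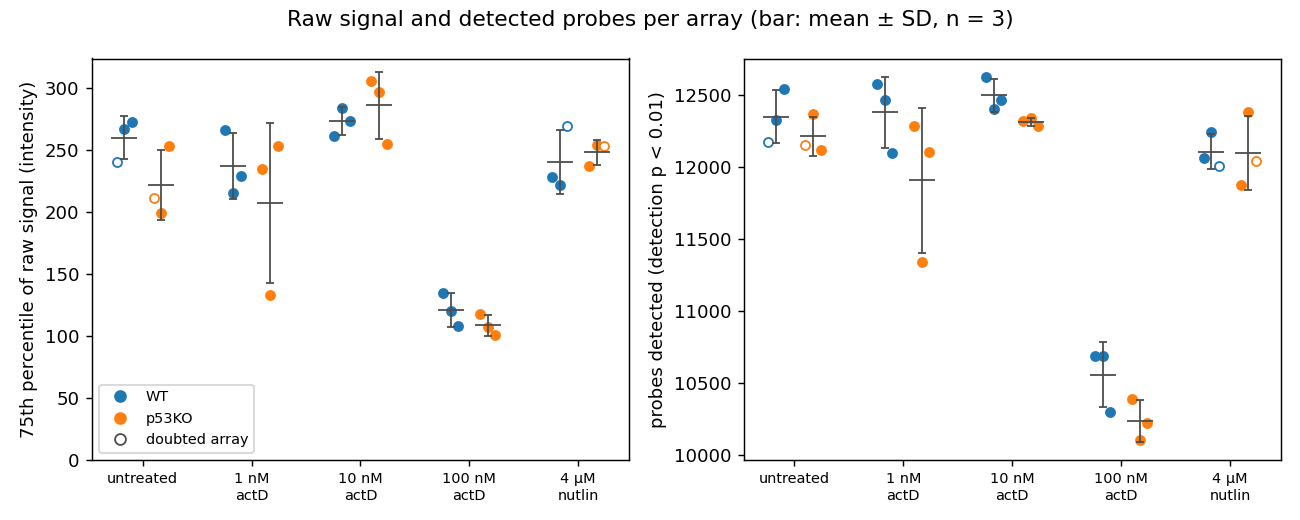
Left: 75th percentile of raw signal per array (intensity, linear axis from 0). Right: probes with a detection p under 0.01 (axis does not start at 0). Points are arrays, bars mean ± SD of 3, open points the 4 doubted arrays. All 100 nM arrays lie between 100.7 and 134.8 at the left and between 10101 and 10690 at the right.

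Genotype labels were checked on genes that differed between the genotypes. PROM1, which encodes a membrane glycoprotein, had a log2 level of 8.81 ± 0.14 (SD, n = 3) in untreated WT cells and 4.31 ± 0.07, not detected on any array, in untreated p53KO cells. It kept those sides on all 24 arrays without nutlin. The array labelled WT nutlin replicate 3 had PROM1 at 4.36, and the array labelled p53KO nutlin replicate 3 had it at 9.07, so these 2 arrays went against their labels. In 75 genes that differed between the genotypes in all 4 other treatments, a score set to 1 for WT and 0 for p53KO was 0.008 on the array labelled WT nutlin replicate 3 and 1.058 on the array labelled p53KO nutlin replicate 3. The first untreated arrays of both genotypes stood apart as well, with FOS, an immediate early transcription factor, at 9.66 in WT against 8.28 and 7.62, and at 11.11 in p53KO against 7.57 and 7.29. Every main value below keeps all arrays as labelled. For the counts of genes and some of the other values, the value without these 4 arrays is given as well.

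**Figure D2:**
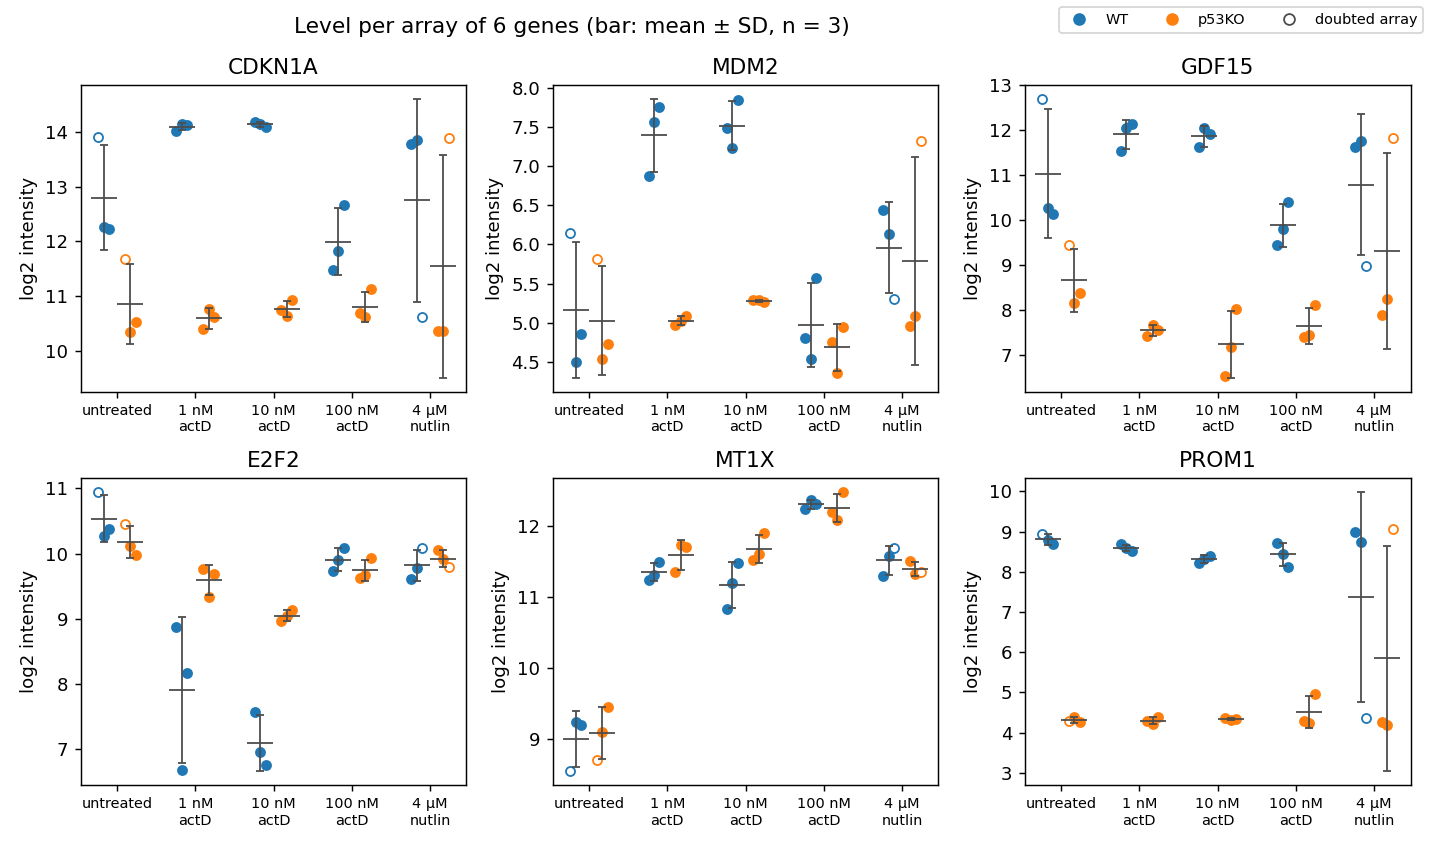
Log2 intensity of CDKN1A, MDM2, GDF15, E2F2, MT1X and PROM1 on each array. Points are arrays, bars mean ± SD of 3, open points the 4 doubted arrays. PROM1 lies at 4.36 on the array labelled WT nutlin replicate 3 and at 9.07 on the array labelled p53KO nutlin replicate 3.

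Untreated WT and p53KO cells differed in 148 genes, 95 higher and 53 lower in WT, of which 87 differed at least 2-fold. PROM1 was at least 16.4-fold higher in WT (adjusted p = 0.019, limma), NRIP1, a nuclear receptor corepressor, at least 11.9-fold (adjusted p = 0.022) and EHF, an epithelial transcription factor, at least 7.29-fold (adjusted p = 0.039). CASP4, an inflammatory caspase, was higher by 3.79 ± 0.81 (log2, SE, adjusted p = 0.025, second probe 0.92), and ADGRF1, an adhesion receptor, by 3.09 ± 0.65 (adjusted p = 0.024, other probes 2.36 and 0.57). ZBED2, a zinc finger gene, differed by -2.88 ± 0.51 (adjusted p = 0.011), SLC2A3, a glucose transporter, by -2.05 ± 0.45 (adjusted p = 0.025), DNER by -1.93 ± 0.47 and SGK1, a stress-induced kinase, by -1.82 ± 0.44, and WNT16 was at least 3.97-fold lower. The repair gene DDB2, a p53 target, was 1.40 ± 0.35 higher in WT (adjusted p = 0.044). CDKN1A, the cell cycle inhibitor p21, differed by 1.94 ± 0.71 (adjusted p = 0.23), and by 1.80 ± 0.24 (adjusted p = 3.8e-05) without the 4 doubted arrays. Without those arrays 401 genes differed, and leaving out 1 array gave 5 to 113. Without the 2 first untreated arrays alone 6 genes differed, which is the same fit as that of slide 4 below. With genotypes paired by number 34 differed, and with pairs and without the 4 arrays 811 did. The first untreated arrays on slide 2, 1 of each genotype with the spread taken from other groups, gave 17 genes, the other 4 untreated arrays on slide 4 gave 6, and slide as a fixed block gave 894. The p53 target lists stood higher in WT (median log2 difference 0.34 for arrest, 0.20 for apoptosis and 0.39 for repair), as did interferon response genes (0.46), and adjusted p = 0.361 to 0.587 with an estimated correlation for these 4 lists.

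In WT cells, 1 nM actinomycin D raised 468 genes and lowered 605, of which 99 and 205 changed at least 2-fold. The 1073 genes became 295 to 1145 on leaving out 1 array and 1998 without the 4 doubted arrays. The genes that rose most were TP53I3, a p53-induced oxidoreductase (2.86 ± 0.85, adjusted p = 0.033), GALNT5, a mucin glycosyltransferase (2.58 ± 0.25, adjusted p = 4.6e-07), SERPINB5, the serpin maspin (2.37 ± 0.39, adjusted p = 3.5e-04), and the metallothionein sequences MT1X (2.34 ± 0.19) and MT1P3 (2.32 ± 0.22). MDM2, which marks p53 for degradation, rose by 2.22 ± 0.47 (adjusted p = 0.0037), ZMAT3 by 1.87 ± 0.50, TIGAR, a regulator of glycolysis, by 1.75 ± 0.22 (adjusted p = 1e-05), FAS, a death receptor, by 1.26 ± 0.30, RRM2B by 1.23 ± 0.31, TNFRSF10A by 1.04 ± 0.33 and BAX by 0.68 ± 0.21. CDKN1A was 1.29 ± 0.71 higher (adjusted p = 0.29) and GDF15, a stress cytokine, 0.88 ± 0.76 higher (adjusted p = 0.55). Without the 4 doubted arrays both rose, CDKN1A by 1.84 ± 0.22 (adjusted p = 7.5e-06) and GDF15 by 1.71 ± 0.31 (adjusted p = 7.3e-04). Among the genes that fell were E2F2 (-2.62 ± 0.32, adjusted p = 1e-05), the origin licensing factor CDT1 (-2.54 ± 0.41), the histone chaperone ASF1B (-2.46 ± 0.38), the cyclin CCNE2 (-2.42 ± 0.44) and DTL (-2.29 ± 0.37). SSBP1 had the lowest change, -5.31 ± 1.31 (adjusted p = 0.012), from levels of 4.11, 4.11 and 11.17 on the 3 arrays, so it did not change alike on all of them.

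As lists, p53 targets rose in WT cells at 1 nM: arrest genes by a median of 0.98 (6 of 19 called, 10 adjusted over the list alone), apoptosis genes by 0.52 (4 of 16, 5 adjusted over the list alone) and repair genes by 0.74 (7 of 16, 11 adjusted over the list alone). Replication genes fell by 1.31 (25 of 35, 29 adjusted over the list alone) and mitosis genes by 0.96 (9 of 34, 29 adjusted over the list alone), with CENPA, a centromere histone, at -1.53 ± 0.49 and TTK, a checkpoint kinase, at -1.47 ± 0.42. Stress response genes of the integrated stress and unfolded protein response fell by 0.84 (12 of 19, 13 adjusted over the list alone), including ASNS (-1.82 ± 0.31) and PHGDH (-1.48 ± 0.19) of amino acid synthesis. The untreated group holds the doubted first array, which was high in the stress genes DDIT3 and PPP1R15A, named outside the rule. DDIT3 lay at 10.48 there against 7.92 and 7.31 on the other untreated arrays, and PPP1R15A at 11.41 against 9.43 and 8.88. Cholesterol synthesis genes fell by 0.46 (2 of 13, 6 adjusted over the list alone), with INSIG1 at -1.89 ± 0.33, and ribosome biogenesis genes rose by 0.34 (4 of 29, 6 adjusted over the list alone). These 8 camera adjusted p-values ran from 1e-26 to 1.32e-04, and adjusted p = 0.113 to 0.221 with an estimated correlation. Without the 4 doubted arrays the 3 p53 lists rose with an estimated correlation too (adjusted p = 0.021, 0.021 and 0.00377). All 1 nM arrays lay on a slide of their own, and with slide as a random block 46 genes were called, among them 0 of 19 arrest, 0 of 16 apoptosis, 1 of 16 repair, 3 of 35 replication, 0 of 34 mitosis, 2 of 19 stress response, 0 of 13 cholesterol and 0 of 29 ribosome biogenesis genes. The medians of those lists were then 0.84, 0.37, 0.71, -1.28, -0.95, -1.03, -0.30 and 0.41.

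At 10 nM in WT cells 1793 genes rose and 1770 fell (2329 and 2256 without the 4 doubted arrays). TP53I3 rose by 3.71 ± 0.85 (adjusted p = 0.0017), GALNT5 by 3.16 ± 0.25 (adjusted p = 7.7e-09), HES2, a transcriptional repressor, by 3.01 ± 0.27, SERPINB5 by 2.98 ± 0.39 and the adhesion gene CEACAM1 by 2.84 ± 0.67. E2F2 fell by 3.43 ± 0.32 (adjusted p = 6.5e-08), as did TIGD5 (-3.13 ± 0.57), CHLSN (-3.12 ± 0.49), DTL (-2.93 ± 0.37) and CCNE2 (-2.87 ± 0.44). MDM2 rose by 2.35 ± 0.47 (adjusted p = 4.9e-04), TIGAR by 2.03 ± 0.22, SESN1 by 2.00 ± 0.54 and FAS by 1.54 ± 0.30, and the mitotic kinase PLK1 fell by 1.20 ± 0.36 (adjusted p = 0.013). CDKN1A was 1.34 ± 0.71 higher (adjusted p = 0.16), and rose by 1.89 ± 0.22 (adjusted p = 1.3e-06) without the 4 doubted arrays. A second, dimmer CDKN1A probe differed by -0.03 at 10 nM and 0.64 at 1 nM. Arrest genes rose by a median of 1.34 (13 of 19, 13 adjusted over the list alone), apoptosis genes by 0.63 (7 of 16, 8 adjusted over the list alone) and repair genes by 0.96 (10 of 16, 12 adjusted over the list alone). Replication genes fell by 1.41 (30 of 35, 30 adjusted over the list alone) and mitosis genes by 1.19 (22 of 34, 25 adjusted over the list alone), of which BUB1B fell by 2.09 ± 0.41 and KIF11 by 2.00 ± 0.42. Stress response genes fell by 0.95 (13 of 19, 13 adjusted over the list alone), including the chaperone HSPA5 (-1.60 ± 0.22), again against an untreated group with the doubted first array. These 6 lists had adjusted p = 0.272 to 0.452 with an estimated correlation, and slide as a random block left 1959 genes called, among them 6 of 19 arrest, 3 of 16 apoptosis, 7 of 16 repair, 27 of 35 replication and 5 of 34 mitosis genes.

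In p53KO cells 1 nM actinomycin D raised 36 genes and lowered 57. The count of 93 became 17 to 193 on leaving out 1 array and 404 (149 higher, 255 lower) without the 4 doubted arrays. MT1P3 rose by 2.56 ± 0.22 (adjusted p = 5.6e-08), MT1X by 2.51 ± 0.19 (adjusted p = 7.4e-09), MT1G by 1.89 ± 0.30, the zinc exporter SLC30A1 by 1.68 ± 0.22 and DHRS2, a dehydrogenase, by 1.68 ± 0.35. UNC5A, a netrin receptor, fell by 1.63 ± 0.21, HSPA5 by 1.39 ± 0.22 (adjusted p = 0.0021), the zinc importer SLC39A10 by 1.31 ± 0.22, SSU72 by 1.28 ± 0.25 and GRAMD4 by 1.27 ± 0.28. CDKN1A (-0.26 ± 0.71, adjusted p = 0.94) and MDM2 (0.00 ± 0.47, adjusted p = 1) were not called. At 10 nM 1204 genes rose and 1287 fell in p53KO cells (1625 and 1664 without the 4 doubted arrays), with MT1X at 2.58 ± 0.19, MT1P3 at 2.36 ± 0.22, DHRS2 at 2.20 ± 0.35, SLC30A1 at 2.13 ± 0.22 and SLC2A3 at 1.93 ± 0.45. CHLSN fell by 3.05 ± 0.49, the nuclear receptor RXRA by 2.85 ± 0.41, TBC1D22A by 2.85 ± 0.36, INPP5A by 2.78 ± 0.45 and TIGD5 by 2.72 ± 0.57. The apoptosis gene PMAIP1 rose without p53 (1.01 ± 0.27, adjusted p = 0.0088), as did MCL1 (1.23 ± 0.26, adjusted p = 0.0015), whose second probe differed by 0.47. Stress response genes fell at both doses in p53KO cells, by a median of 0.68 (2 of 19, 15 adjusted over the list alone) and 0.80 (9 of 19, 12 adjusted over the list alone), and ribosome biogenesis genes rose by 0.27 (2 of 29, 10 adjusted over the list alone) and 0.23 (9 of 29, 10 adjusted over the list alone), with an estimated-correlation adjusted p of 0.049 for the last list at 1 nM and of 0.0898 to 0.684 for the others. The untreated p53KO group, too, holds a doubted first array that was high in DDIT3 and PPP1R15A, named outside the rule. DDIT3 lay at 10.08 there against 8.55 and 8.15 on the other untreated arrays, and PPP1R15A at 12.38 against 9.67 and 9.22. With slide as a random block 5 genes were called at 1 nM and 949 at 10 nM, among them 0 and 8 of 19 stress response genes, and of 29 ribosome biogenesis genes 0 at 1 nM and 2 higher and 1 lower at 10 nM.

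Whether the response differed between genotypes was tested as an interaction. At 1 nM limma called 0 genes, with 709 at an unadjusted p under 0.05. MDM2 responded by 2.23 ± 0.66 more in WT cells (adjusted p = 0.34) and CDKN1A by 1.54 ± 1.01 more (adjusted p = 1). As lists the difference passed camera's test: the response of arrest genes was 1.12 higher in WT (median of 19), of apoptosis genes 0.58 (16) and of repair genes 0.86 (16), and that of replication genes was -1.21 (35) and of mitosis genes -1.12 (34), with adjusted p = 4.3e-35 to 7.66e-09, and adjusted p = 0.0694 to 0.113 with an estimated correlation. The pairing alone called 1 gene, leaving out the first untreated arrays alone 1, leaving out the third nutlin arrays alone 55 and slide as a random block 21. Without the 4 doubted arrays 101 genes had a higher log2 change in WT and 19 a lower one, and with pairs as well 199 and 103. In that paired fit MDM2 responded by 2.32 ± 0.26 more (adjusted p = 6.8e-04), CDKN1A by 1.68 ± 0.19 (adjusted p = 8.9e-04), GDF15 by 2.42 ± 0.29 (adjusted p = 8.9e-04) and TP53I3 by 2.96 ± 0.28 (adjusted p = 4.4e-04), 14 of 19 arrest genes were called higher, and 18 of 35 replication genes lower. Slide as a fixed block, which sets the genotypes against each other within slides, called 154 genes, including CDKN1A (1.54 ± 0.28, adjusted p = 0.0091) and MDM2 (2.23 ± 0.32, adjusted p = 0.003). The third nutlin arrays lay alone on slides 6 and 7, so this block fits each of them exactly. They add nothing to its estimates or its spread, so in effect it leaves them out.

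At 10 nM the log2 change was higher in WT than in p53KO cells for 28 genes and lower for 21. CYP4F3, a fatty acid hydroxylase, responded by 2.98 ± 0.54 more (adjusted p = 0.01), and SUGCT by 2.64 ± 0.55. MYBPHL (2.55 ± 0.33), KLHL30 (2.48 ± 0.26) and SMTNL2 (1.92 ± 0.23) rose in WT cells and were not detected in p53KO cells at 10 nM (interaction adjusted p = 0.012, 0.0019 and 0.0019). The listed p53 targets PGF (1.92 ± 0.35) and TIGAR (1.66 ± 0.30) were also called. The log2 change was lower in WT than in p53KO cells for DTL (-2.39 ± 0.53), E2F2 (-2.29 ± 0.45) and FBXO5, an inhibitor of the anaphase-promoting complex (-2.28 ± 0.51). It was also lower for ORC1 of the origin recognition complex (-1.98 ± 0.45), E2F8 (-1.83 ± 0.42) and E2F1 (-1.49 ± 0.33). DTL and E2F2 fell in WT cells at 10 nM, and by more than in p53KO cells. The response of arrest genes was 1.16 higher, of apoptosis genes 0.57 and of repair genes 0.94, and that of replication genes was -1.27 and of mitosis genes -1.45 (camera adjusted p = 3.54e-29 to 1.37e-08, and adjusted p = 0.077 to 0.0854 with an estimated correlation). The count was 15 in the authors' processed table, 15 without the second WT arrays at 10 and 100 nM, 21 with probes detected on all arrays and 27 (24 higher, 3 lower) without the first untreated arrays. Leaving out 1 array gave 20 to 75, the highest with 27 higher and 48 lower. Slide as a random or fixed block called 146 and 345 genes, and pairing alone 167. Without the 4 doubted arrays the counts were 196 and 104, and with pairs as well 407 and 340.

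Nutlin in WT cells, with arrays as labelled, raised 14 genes and lowered 13. MT1X rose by 2.51 ± 0.19 (adjusted p = 1.4e-08), MT1P3 by 2.03 ± 0.22, GALNT5 by 1.52 ± 0.25 (adjusted p = 0.0049), the growth factor FGF9 by 1.44 ± 0.31 and MT1G by 1.41 ± 0.30. SLC39A10 fell by 1.27 ± 0.22, FAM111A by 1.15 ± 0.21, CABLES2 by 1.05 ± 0.22, PCK2 by 0.95 ± 0.20 and the cysteinyl-tRNA synthetase CARS1 by 0.93 ± 0.16. CDKN1A (-0.05 ± 0.71, adjusted p = 0.99) and MDM2 (0.79 ± 0.47, adjusted p = 0.52) were not called. These values hold the array labelled WT nutlin replicate 3, on which CDKN1A was 10.62 against 13.78 and 13.85 on the others. Without the 4 doubted arrays 148 genes rose and 166 fell, with 2 arrays on each side: TP53I3 rose by 2.73 ± 0.50 (adjusted p = 0.0061), MDM2 by 1.61 ± 0.28 (adjusted p = 0.0038), CDKN1A by 1.57 ± 0.24 (adjusted p = 0.0013) and GDF15 by 1.49 ± 0.34 (adjusted p = 0.025). In that fit arrest genes rose by a median of 0.71 (8 of 19, 12 adjusted over the list alone) and mitosis genes fell by 1.05 (1 of 34, 30 adjusted over the list alone), with adjusted p = 0.108 and 0.266 with an estimated correlation. Its nutlin arrays lay on slide 2 and its untreated arrays on slide 4, in both genotypes, so it cannot tell nutlin from slide. On slide 2, where nutlin arrays 1 and 2 meet only the doubted first untreated array and the spread comes from other groups, 416 genes were called, and slide as a random or fixed block called 904 and 2271. The deviation of that untreated array enters all 3 counts.

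In p53KO cells nutlin raised 5 genes and lowered 1 (4 and 0 without the 4 doubted arrays), including MT1X (2.30 ± 0.19, adjusted p = 4.3e-08), MT1P3 (2.18 ± 0.22), MT2A (1.51 ± 0.13), SLC30A1 (1.13 ± 0.22) and SLC39A10 (-1.16 ± 0.22). With slide as a random or fixed block 952 and 2214 genes were called, with 14 and 17 of 24 immediate early genes and 8 and 15 of 19 stress response genes lower. Those blocks lean on slide 2, where the only untreated p53KO array is the doubted one. The array labelled p53KO nutlin replicate 3 had CDKN1A at 13.89 against 10.38 and 10.38 on the others. The interaction called 0 genes in limma, 268 at an unadjusted p under 0.05. It also called 0 without the 4 doubted arrays, and with pairs as well 12, all higher in WT, among them TP53I3 (2.63 ± 0.31, adjusted p = 0.006), CDKN1A (1.64 ± 0.21, adjusted p = 0.013), ACTA2 (1.69 ± 0.19), SERPINB5 (1.75 ± 0.25) and CYFIP2 (1.43 ± 0.21), of which ACTA2, SERPINB5 and CYFIP2 were named after their values were seen. With arrays as labelled, the response of replication genes to nutlin was -0.38 in WT minus p53KO and that of interferon genes -0.27 (adjusted p = 1.69e-05 and 2.87e-04, and adjusted p = 0.83 for both with an estimated correlation). With pairs and without the 4 doubted arrays, the median was -0.73 for replication and -0.07 for interferon genes.

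Low-dose actinomycin D and nutlin shared 24 genes in WT cells, 11 higher and 13 lower in both, where independent lists would share 0.568 and 0.682, and 100 simulations of unchanged groups against the same untreated arrays, which hold no effect to call, shared at most 0. Neither value covers real effects and shared arrays together. They shared 226 without the 4 doubted arrays, 115 higher and 111 lower, against 11.9 and 15.4 for independent lists, and 1 gene moved in opposite directions. Across genes the fold changes correlated at 0.54 (0.5 in unchanged simulated groups) with a covariance of 0.0636 (0.0229 simulated), and without the 4 arrays at 0.67 (0.55) with a covariance of 0.101 (0.0217). Both comparisons used the same untreated arrays, too few to split between them. Set against each other, 1 nM actinomycin D was higher than nutlin in 160 genes and lower in 245. These numbers were 354 and 465 without the 4 doubted arrays. CYP4F3 (1.59 ± 0.38), KLHL30 (1.57 ± 0.26), PMAIP1 (1.47 ± 0.27, adjusted p = 0.0039), the ubiquitin ligase RNF19B (1.42 ± 0.25) and FAS (1.37 ± 0.30) were higher with actinomycin D. TIGD5 (-2.06 ± 0.57), CDT1 (-1.93 ± 0.41), E2F2 (-1.91 ± 0.32) and CCNE2 (-1.80 ± 0.44) were lower, as was SSBP1 (-5.43 ± 1.31) on 2 of 3 arrays. All these values hold the array labelled WT nutlin replicate 3, which went against its genotype label, so they are not differences between the drugs alone. Without the 4 doubted arrays PMAIP1 (1.75 ± 0.23), FAS (1.01 ± 0.21) and MDM2 (1.10 ± 0.26, adjusted p = 0.013) were higher with actinomycin D, while CDKN1A was not called (0.27 ± 0.22, adjusted p = 0.51). With slide as a random block 0 genes differed.

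At 100 nM the raw signal fell in both genotypes, so changes are relative to the array. In WT cells 3829 genes were higher and 3749 lower, and in p53KO cells 3898 and 3719. The numbers without the 4 doubted arrays were 3991 and 3927 in WT and 4038 and 3944 in p53KO cells. Under 75th percentile scaling the median of all genes lay 0.54 higher in WT and 0.56 in p53KO cells, and 71.7% and 71.3% of calls were higher, against 50.5% and 51.2%. Relative to the array, the matricellular gene CCN2 rose by 4.89 ± 0.70 in WT (adjusted p = 1.5e-06), C1orf162 by 4.48 ± 0.30, the small GTPase REM2 by 4.45 ± 0.19, LINC00324 by 4.33 ± 0.20 and SGK1 by 4.29 ± 0.44. HS3ST1 fell by 4.56 ± 0.20 and TTK by 4.42 ± 0.42, and ARHGAP12, CENPA and IWS1 were at least 12.8-, 11.8- and 15.4-fold lower. In p53KO cells C1orf162 rose by 3.84 ± 0.30, REM2 by 3.82 ± 0.19, the histone H2BC21 by 3.80 ± 0.27, C9orf152 by 3.79 ± 0.19 and GPR3 by 3.76 ± 0.24. HS3ST1 fell by 4.06 ± 0.20, and ZMIZ1, LRRC1, CENPA and FUT8 were at least 11.3-, 12.6-, 14.2- and 8.39-fold lower, with a second LRRC1 probe at -1.38. FOSB rose by 3.71 ± 0.65 in WT and 3.35 ± 0.65 in p53KO cells and FOS by 1.85 ± 0.70 in each, while MYC fell by 1.20 ± 0.21 and 0.65 ± 0.21, the latter at 0.02 under 75th percentile scaling.

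CDKN1A (-0.81 ± 0.71), MDM2 (-0.20 ± 0.47), GDF15 (-1.15 ± 0.76) and FAS (-0.64 ± 0.30) were not called at 100 nM in WT cells (adjusted p = 0.32, 0.73, 0.19 and 0.066), whereas PMAIP1 (2.57 ± 0.27), PLK2 (2.21 ± 0.19) and BAX (0.70 ± 0.21) rose. Set against 1 nM, 100 nM left MDM2 at -2.42 ± 0.47 (adjusted p = 7.6e-05), CDKN1A at -2.09 ± 0.71 (adjusted p = 0.012, second probe -0.56), GDF15 at -2.03 ± 0.76, FAS at -1.90 ± 0.30 and MYC at -1.74 ± 0.21, and raised BIRC5, which encodes survivin, by 3.91 ± 0.36 and E2F1 by 2.54 ± 0.23. In that comparison 3842 genes were higher and 3751 lower (4274 and 4120 without the 4 doubted arrays). SGK1 (4.67 ± 0.44), C1orf162 (4.64 ± 0.30), LINC00324 (4.38 ± 0.20) and REM2 (4.32 ± 0.19) were the highest with TCERG1L, at least 14.6-fold. ARHGAP12, PLEKHG3, RCL1 and IWS1 were at least 16.5-, 14.1-, 13.2- and 16.5-fold lower, and HS3ST1 fell by 4.25 ± 0.20. Mitosis genes fell against untreated cells by a median of 1.28 in WT (26 of 34, 26 adjusted over the list alone) and 1.25 in p53KO cells (24 of 34, 27 adjusted over the list alone). Ribosome biogenesis genes fell by 0.61 (16 of 29, 16 adjusted over the list alone) and 0.77 (17 of 29, 17 adjusted over the list alone). These 4 list tests had adjusted p = 0.486 to 0.995 with an estimated correlation. The falls of ribosome biogenesis genes were not far above the rise of the median of all genes under 75th percentile scaling, so their size depends on the scaling.

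The response to 100 nM differed between genotypes in 27 genes, 21 of them higher in WT. TCERG1L, a transcription elongation regulator homologue, had a level of 8.61 ± 0.08 (SD, n = 3) in WT cells at 100 nM and was not detected in any other group, a rise of at least 14.5-fold in WT (interaction adjusted p = 5.8e-17). SNAI2, a repressor of epithelial genes, and LHX5 rose at least 6.40- and 3.91-fold in WT and were not detected in p53KO cells at 100 nM (interaction adjusted p = 1.2e-06 and 0.012). The response of FBXW7, a ubiquitin ligase subunit, was higher in WT by 2.26 ± 0.24 (adjusted p = 4.6e-06, other probes 0.65 and 1.21) and of AKAP19 by 2.09 ± 0.37. FZD4, a Wnt receptor, and IWS1 fell at least 2.70- and 15.4-fold in WT, where they were not detected at 100 nM, and differed by -0.63 ± 0.16 and -3.43 ± 0.13 (log2, SE) in p53KO cells (interaction adjusted p = 0.0043 and 0.031). Under 75th percentile scaling 6 genes were called, all higher in WT. TCERG1L, SNAI2 and FBXW7 were kept, and AKAP19, LHX5, FZD4 and IWS1 were lost. With probes detected on all arrays 3 genes were called, all higher. Other fits called more genes and were less one-sided. They gave 51 higher and 37 lower without the 4 doubted arrays, and 91 and 55 with pairs as well. Slide as a fixed block gave 61 and 43, no filter on dim probes 27 and 21, and leaving out WT 100 nM replicate 1 gave 31 and 19. No list passed camera's test in this interaction.

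Of the other lists, ribosomal protein genes had medians from -0.02 to 0.04 over the 8 treatments, and heat shock genes from -0.37 to 0.05, with none past camera's test. Immediate early genes had medians of 1.16 and 0.95 at 100 nM in WT and p53KO cells, not past camera's test, and 1.36 and 1.43 without the 4 doubted arrays, which passed (adjusted p = 0.00104 and 0.00283, and adjusted p = 0.535 and 0.516 with an estimated correlation). The interferon list fell in WT cells at 1 nM (-0.45) and with nutlin (-0.45), and the NF-kB list fell with nutlin in p53KO cells (-0.40), with adjusted p = 0.344 to 0.7 with an estimated correlation. The NF-kB value holds the doubted first untreated p53KO array. There CXCL8 lay at 8.44 against 4.73 and 5.29 on the other untreated arrays, and TNFAIP3 at 8.60 against 5.64 and 5.87. Nutlin arrays 1 and 2 had CXCL8 at 4.76 and 5.37 and TNFAIP3 at 5.62 and 5.65. Both genes were named outside the rule. Colon epithelial markers had medians from 0.02 to 0.17. Of 22 markers of other cell types 4 were tested, and their median rose by 2.10 in WT and 1.82 in p53KO cells at 100 nM (4 of 4 called in each, adjusted p = 0.343 and 0.254 with an estimated correlation), with HBA1 at 2.67 ± 0.33 in WT and 2.61 ± 0.33 in p53KO cells.

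**Figure D3:**
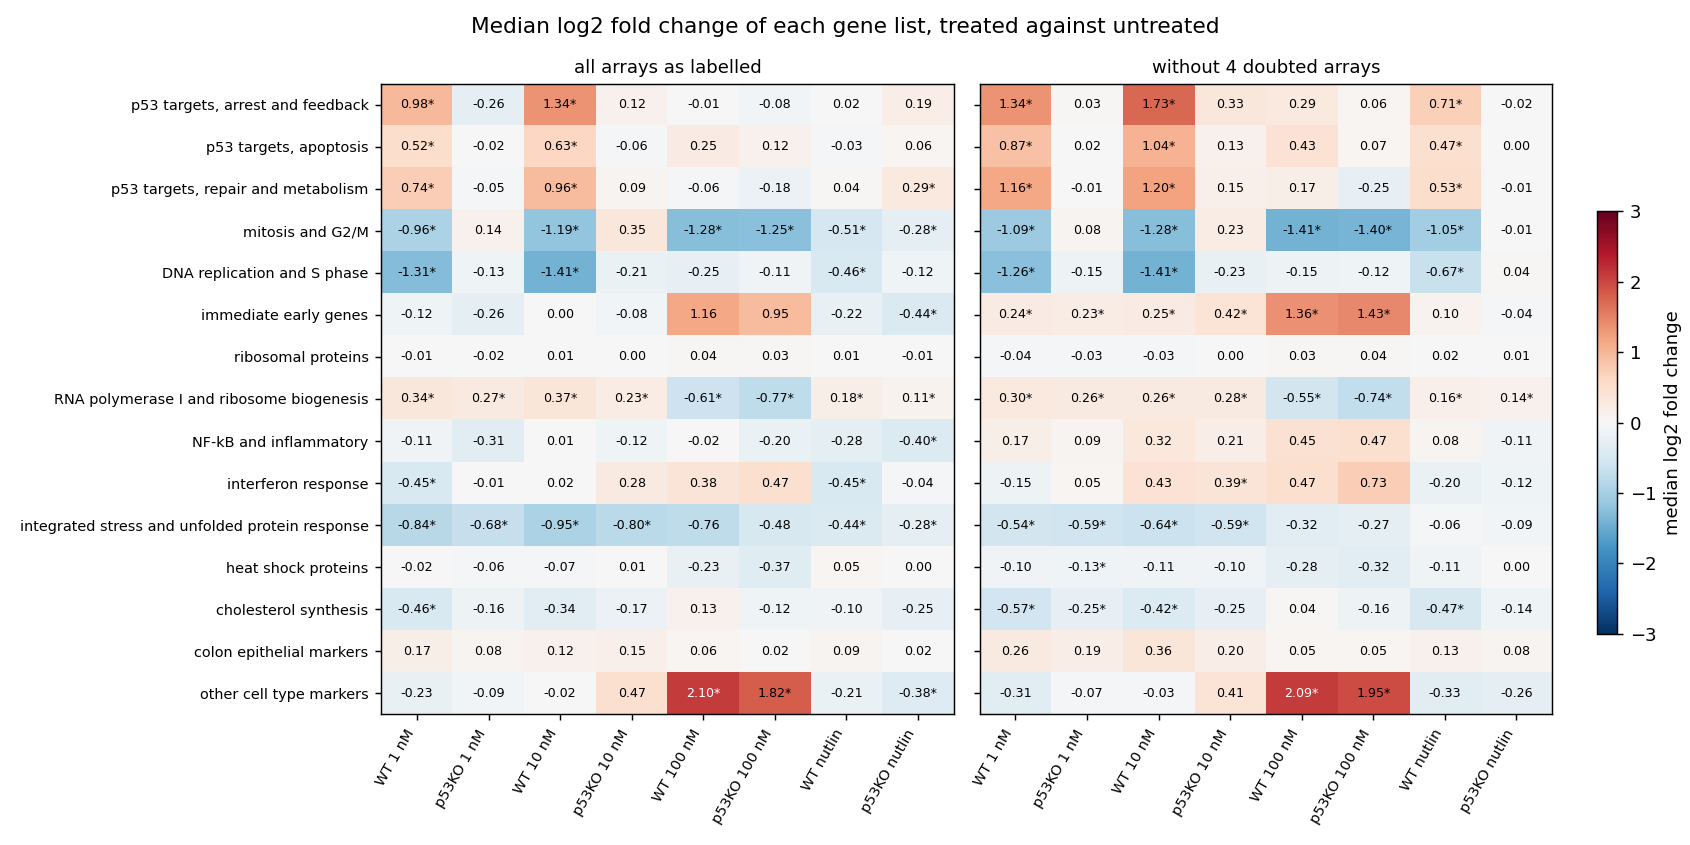
Median log2 fold change of each gene list (y axis) in each treatment against the untreated cells of its genotype (x axis), with all arrays as labelled (left) and without the 4 doubted arrays (right). A star marks a camera adjusted p under 0.05 at the preset correlation. Arrest genes stand at 0.98 in WT and -0.26 in p53KO cells at 1 nM at the left.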

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

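The tests of the doubted arrays and the other splits of the arrays in this part were chosen only after the results were seen, and the tests of the interactions had been set before. Each result here is a difference between the responses of WT and p53KO cells that passed its test with all arrays as labelled.

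At 1 nM actinomycin D the response in WT minus that in p53KO cells had a median of 1.12 in the arrest list, 0.58 in the apoptosis list, 0.86 in the repair list, -1.12 in the mitosis list, -1.21 in the replication list, -0.20 in the interferon list and -0.20 in the cholesterol list. At 10 nM the medians were 1.16 for arrest, 0.57 for apoptosis, 0.94 for repair, -1.45 for mitosis and -1.27 for replication, and for nutlin -0.38 for replication and -0.27 for interferon genes. With an estimated correlation none of these passed: adjusted p was 0.0694 to 0.113 for the p53, mitosis and replication lists at 1 nM, 0.493 for the interferon and cholesterol lists there, 0.077 to 0.0854 at 10 nM and 0.83 for nutlin. The nutlin medians hold the nutlin arrays that went against their genotype labels. With genotypes paired by number and without the 4 doubted arrays, the nutlin median was -0.73 for replication and -0.07 for interferon genes. Single genes passed at 10 nM in 49 cases, among them CYP4F3 (2.98), SUGCT (2.64), MYBPHL (2.54), KLHL30 (2.42), SMTNL2 (2.19), PGF (1.92), TIGAR (1.66), E2F1 (-1.49), E2F8 (-1.83), ORC1 (-1.98), FBXO5 (-2.28), E2F2 (-2.29) and DTL (-2.39). At 100 nM 27 genes passed, among them TCERG1L (4.19), SNAI2 (2.89), FBXW7 (2.26), AKAP19 (2.09), LHX5 (1.63), IWS1 (-0.86), FAM184A (-0.99) and FZD4 (-1.33). The values of KLHL30, MYBPHL, SMTNL2, TCERG1L, SNAI2, LHX5, IWS1, FAM184A and FZD4 rest in part on groups where the probe was not detected, so they are not folds.

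Of 100 drawn splits of the 12 arrays of each interaction, 16 gave at least 49 genes at 10 nM (highest other 2272) and 15 gave at least 27 at 100 nM (highest other 8816), which does not exclude chance. Nor do these splits speak for it, since most break the pairs of WT and p53KO arrays. The 10 splits that regroup both genotypes alike, and so keep all 6 pairs, were too few for a share under 0.05. They gave 49 and 27 genes in the real split and 0 as the highest other for both. At 1 nM and for nutlin 0 genes were called, which all 100 splits reached (highest other 882 and 801). The splits with the most genes at each dose and for nutlin moved most labels of 1 genotype but not of the other, which adds the effects of treatment instead of subtracting them, a structure of the arrays. Of the splits without that feature 5 gave at least 49 genes at 10 nM and 1 gave at least 27 at 100 nM, and the most at 1 nM and for nutlin were 35 and 39. The 5 at 10 nM and the 1 at 100 nM kept all 3 treated WT arrays and 2 of 3 treated p53KO arrays. They thus lie close to the real split and keep most of its treatment effect.

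The third nutlin arrays of both genotypes went against their genotype labels. An exchange of these 2 arrays between the genotypes may account for this, since the array labelled WT nutlin replicate 3 scored 0.008, inside the p53KO range of -0.06 to 0.055, and its partner scored 1.058, inside the WT range of 0.846 to 1.128 (12 arrays each). Those same scores argue against a mixture of RNA, which would put both between the ranges. A change of signal by slides 6 and 7 alone, which hold 1 of these arrays each, is argued against too. At most 6.9% of 10261 genes outside the score lay at least 1 log2 unit from the other arrays of the label. Of the 75 score genes 89.3% and 90.7% did. No such share was taken for other arrays, so a slide effect beside an exchange is not excluded. The arrays were not exchanged in any value given here, and no biological explanation was tested.

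The first untreated arrays of both genotypes differed from the other 2 of their genotype by at least 1 log2 unit in 186 genes that were higher and 113 that were lower in both, with ATF3 at 11.42 against 8.49 and 7.84 in WT and at 11.30 against 8.38 and 7.99 in p53KO cells. A change of signal by slide 2 is argued against by the 4 nutlin arrays on it, shifted by a mean of 0.15 (0.01 to 0.25) in these genes against 1.30 and 1.36 for the first untreated arrays. RNA of 100 nM cultures mixed into these samples is argued against by 34 of the 186 genes, which lay at least 1 log2 unit above every 100 nM array and both other untreated arrays in both genotypes, such as CXCL8 (8.44 in p53KO against a mean of 6.74 at 100 nM). That these cultures were handled apart from the others could account for it and stays open, since the deviations correlated at 0.78 between the genotypes but no label describes handling. No biological explanation was tested.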

How the results depend on the processing

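The alternatives without doubted arrays, within 1 slide or with paired genotypes, and slide as a fixed block for single genes, were chosen only after the data were seen, except the gene counts of nutlin comparisons without the third nutlin arrays. Counts under an alternative stayed within 1.5 times the main count in 265 cases and did not in 144. The 69 list results that passed their test kept camera's direction and passed in 324 cases, and kept the direction without passing in 155. In 4 cases camera's direction changed, which need not change the sign of the median. Named genes did not change their call in 3730 cases, lost it in 570, gained it in 63 and changed sign in 7. In 62 of the unchanged cases the sign differed but neither fit called the gene. List tests passed in 69 of 225 pairs of list and contrast, in 1 with an estimated correlation, in 52 with fry, 83 with its mixed test and 79 without the 4 doubted arrays. Array weights were lowest on the 4 doubted arrays (0.16 to 0.21). The lower signal at 100 nM limited what quantile scaling compared, and 75th percentile scaling moved the share of calls that were higher from 50.5% to 71.7% in WT, from 51.2% to 71.3% in p53KO cells and from 50.6% to 71.1% for 100 against 1 nM. The cause of the changes below was not tested beyond what follows. Fewer arrays or groups leave fewer degrees of freedom, which cannot raise a count. Without the third nutlin arrays, contrasts that hold no nutlin group keep their group means, and residual degrees of freedom go from 20 to 18. Their counts rose all the same, at 1 nM in WT cells from 1073 to 1682. That leaves the spread shared by all groups, into which these 2 arrays enter.

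With array weights, 1 nM in WT gave 3379, 10 nM in WT 5706, nutlin in WT 1854, 1 nM in p53KO 2576, 10 nM in p53KO 6584, nutlin in p53KO 25, 1 nM interaction 876, 10 nM interaction 1554, 100 nM interaction 133, nutlin interaction 8, WT against p53KO 1231, 1 nM against nutlin 3091. With slide as a random block, 1 nM in WT gave 46, 10 nM in WT 1959, nutlin in WT 904, 1 nM in p53KO 5, 10 nM in p53KO 949, nutlin in p53KO 952, 1 nM interaction 21, 10 nM interaction 146, 100 nM interaction 53, WT against p53KO 454, 1 nM against nutlin 0. Without the third nutlin arrays, 1 nM in WT gave 1682, nutlin in WT 167, 1 nM in p53KO 261, 1 nM interaction 55, 10 nM interaction 250, 100 nM interaction 72, WT against p53KO 532, genes shared by 1 nM and nutlin 131. Without all 4 doubted arrays, 1 nM in WT gave 1998, nutlin in WT 314, 1 nM in p53KO 404, 1 nM interaction 120, 10 nM interaction 300, 100 nM interaction 88, WT against p53KO 401, 1 nM against nutlin 819, genes shared by 1 nM and nutlin 226. With only the groups of the contrast, 1 nM in WT gave 277, nutlin in WT 3, 1 nM in p53KO 6, 1 nM interaction 2, 10 nM interaction 357, 100 nM interaction 10, 1 nM against nutlin 0. With 75th percentile scaling, nutlin in WT gave 52, 1 nM in p53KO 48, 10 nM interaction 85, 100 nM interaction 6. With no background correction, nutlin in WT gave 44, 1 nM interaction 1. With an offset of 50, nutlin in WT gave 45, 1 nM interaction 1. With the authors' processed table, nutlin in WT gave 16, 1 nM in p53KO 61, 10 nM interaction 15, WT against p53KO 94, genes shared by 1 nM and nutlin 15. With the series matrix, nutlin in WT gave 16, 1 nM in p53KO 61, 10 nM interaction 15, WT against p53KO 94. With probes detected on all arrays, nutlin in WT gave 46, 1 nM interaction 1, 10 nM interaction 21, 100 nM interaction 3, WT against p53KO 70. With slide as a fixed block, nutlin in WT gave 2271, nutlin in p53KO 2214, 1 nM interaction 154, 10 nM interaction 345, 100 nM interaction 104, WT against p53KO 894. With replicate number as a block, nutlin in WT gave 54, 1 nM in p53KO 160, nutlin in p53KO 10, genes shared by 1 nM and nutlin 43. With slide 2 alone, nutlin in WT gave 416, nutlin in p53KO 801, nutlin interaction 2, WT against p53KO 17. Without the first untreated arrays, 1 nM in p53KO gave 175, 1 nM interaction 1, 10 nM interaction 27, WT against p53KO 6, 1 nM against nutlin 734. With the genotypes paired as a block, 1 nM interaction gave 1, 10 nM interaction 167, 100 nM interaction 43, nutlin interaction 1, WT against p53KO 34. With that paired block and without the third nutlin arrays, 1 nM interaction gave 514, 10 nM interaction 1029, 100 nM interaction 292, nutlin interaction 4, WT against p53KO 1633. With the paired block and none of the 4 doubted arrays, 1 nM interaction gave 302, 10 nM interaction 747, 100 nM interaction 146, nutlin interaction 12, WT against p53KO 811. Without the second WT 10 nM and WT 100 nM arrays, 10 nM interaction gave 15. With no filter on dim probes, 100 nM interaction gave 48, WT against p53KO 82. With slide 4 alone, which for WT against p53KO is the same fit as without the first untreated arrays, the count was 6.

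With nutlin in p53KO cells the median of repair genes was -0.02 without the third nutlin arrays and -0.01 without all 4 doubted arrays (0.29 with all), and that of mitosis genes 0.09 and -0.01 (-0.28 with all). In WT cells with nutlin CDKN1A was 1.57 and GDF15 1.49 without all 4 doubted arrays (-0.05 and -0.25 with all). CDKN1A was -1.45 and MDM2 -0.89 in p53KO cells with nutlin and slide as a fixed block (0.69 and 0.76 without it). The nutlin interaction of CDKN1A was 1.5 with the paired block without the third nutlin arrays and 1.64 with the paired block without all 4 (-0.74 with all). MYC in p53KO cells at 100 nM was 0.02 with 75th percentile scaling (-0.65 with quantile scaling).

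Leaving out each array in turn gave, as lowest and highest counts, 1 nM against nutlin 60 to 470, 1 nM in WT 295 to 1145, 10 nM in WT 2770 to 3362, 100 against 1 nM 7035 to 7381, 100 nM in WT 6964 to 7390, nutlin in WT 8 to 43, WT against p53KO 5 to 113, 1 nM in p53KO 17 to 193, 10 nM in p53KO 1656 to 2210, 100 nM in p53KO 7096 to 7314, nutlin in p53KO 4 to 6, 1 nM interaction 0 to 50, 10 nM interaction 20 to 75, 100 nM interaction 21 to 50, nutlin interaction 0 to 1, genes shared by 1 nM and nutlin 7 to 32. 1 nM in WT had 295 without WT 1 nM replicate 2, 597 without WT 1 nM replicate 3. Nutlin in WT had 9 without WT nutlin replicate 1, 8 without WT untreated replicate 2, 43 without WT nutlin replicate 3. 1 nM in p53KO had 193 without p53KO 1 nM replicate 1, 17 without p53KO 1 nM replicate 2, 32 without p53KO 1 nM replicate 3, 42 without p53KO untreated replicate 2, 27 without p53KO untreated replicate 3. 10 nM in p53KO had 1656 without p53KO 10 nM replicate 2. 1 nM interaction had 3 without WT untreated replicate 1, 50 without WT 1 nM replicate 1. 10 nM interaction had 20 without WT 10 nM replicate 2, 23 without WT untreated replicate 2, 25 without WT untreated replicate 3, 28 without p53KO untreated replicate 2, 26 without p53KO untreated replicate 3, 75 without WT 10 nM replicate 1, 21 without p53KO 10 nM replicate 1, 24 without p53KO 10 nM replicate 2, 21 without WT 10 nM replicate 3, 20 without p53KO 10 nM replicate 3. 100 nM interaction had 50 without WT 100 nM replicate 1. Nutlin interaction had 1 without p53KO nutlin replicate 1, 1 without WT untreated replicate 3. WT against p53KO had 5 without p53KO untreated replicate 1, 8 without WT untreated replicate 2, 17 without WT untreated replicate 3, 14 without p53KO untreated replicate 2, 21 without p53KO untreated replicate 3. 1 nM against nutlin had 60 without WT 1 nM replicate 2, 189 without WT 1 nM replicate 3, 181 without WT nutlin replicate 3. Genes shared by 1 nM and nutlin had 9 without WT nutlin replicate 1, 7 without WT untreated replicate 2.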

Other observations

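The tests of metallothionein genes and of other splits of the arrays were chosen only after the results were seen, as were SSBP1 and the zinc genes outside the naming rule.

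The metallothionein genes MT1X and MT2A, whose products bind zinc and copper, rose with every treatment, while MT1E, MT1F and MT1G were each called in only some of them. MT1X rose by 2.34 ± 0.19 (SE) at 1 nM, 2.15 ± 0.19 at 10 nM, 3.29 ± 0.19 at 100 nM and 2.51 ± 0.19 with nutlin in WT cells (3 arrays per group), and by 2.51 ± 0.19, 2.58 ± 0.19, 3.16 ± 0.19 and 2.30 ± 0.19 in p53KO cells. MT2A rose by 1.27 ± 0.13, 0.80 ± 0.13, 1.20 ± 0.13 and 1.36 ± 0.13 in WT cells, and the zinc exporter SLC30A1 by 2.11 ± 0.22, 2.71 ± 0.22, 2.22 ± 0.22 and 1.01 ± 0.22. The zinc importer SLC39A10 fell by 0.88 ± 0.22, 0.92 ± 0.22, 1.08 ± 0.22 and 1.27 ± 0.22 in WT cells. Of 9 genes listed after these values were seen 7 were tested, of which 4 to 7 were called in each treatment, with medians of 0.92 to 2.16 in the direction of the list.

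A slide effect in the nutlin groups is argued against by slide 2, on which the median change of these 7 genes in both genotypes was 1.03 (quartiles 0.84 and 1.44). That rests on 2 nutlin arrays and 1 untreated array per genotype, the latter doubted, with the spread for tests taken from other groups: MT1X rose by 2.88 ± 0.26 in WT and 2.70 ± 0.27 in p53KO cells there, while SLC39A10 was not called. A need for p53 is argued against by p53KO cells, where the median change at 1 nM was 1.56. Handling, medium or vehicle that differed between treated and untreated cultures could account for the pattern and stays open, since all 8 treated groups lay apart from the untreated arrays in MT1X and the labels describe no vehicle. A response of the cells to both drugs is the biological alternative, a hypothesis that the design cannot tell apart from a vehicle.

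SSBP1, a mitochondrial DNA-binding protein, lay at 4.11 on the first p53KO array at 1 nM against 10.88 and 11.04 on the others, as on 2 WT arrays of the same slide, and between 10.91 and 12.02 on all arrays of other slides.

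With 3 arrays against 3 there were 10 splits, too few for a share under 0.05. The real split gave the most genes, and 1 split reached its count, in WT cells at 1 nM (1073, highest other 0), 10 nM (3563, highest other 0) and 100 nM (7578, highest other 6), in p53KO cells at 1 nM (93, highest other 6), 10 nM (2491, highest other 0), 100 nM (7617, highest other 7) and with nutlin (6, highest other 0), for 1 nM against nutlin (405, highest other 0) and for 100 against 1 nM (7593, highest other 4). For nutlin in WT cells 2 splits gave at least 27 genes, and the higher, 43, set the 3 arrays of slide 2 against the rest, while 416 genes were called within that slide. For untreated WT against p53KO cells 5 splits gave at least 148 genes, and the 4 others (highest other 377) all put the first untreated arrays of both genotypes together, parting 1 pair. Among the splits that part all 3 pairs, the other 3 gave 0 genes.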
